A study of Mus musculus with 4 samples.

How the data were processed

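Poly(A) RNA libraries were made from V6.5 mouse embryonic stem cells carrying a degron on RPB3, per the labels' protocols, after doxycycline alone (untreated, 2 libraries) or after doxycycline followed by IAA (2 libraries). The labels list the molecule as total RNA and describe a poly(A) library from it. Each library's group and replicate number came from its title. The sample labels give 12 h of IAA, whereas another sentence of the treatment protocol speaks of depletion for 1 h. The 12 h of the sample labels is used here, and the difference is unresolved. Drosophila S2 cells were added as a spike-in, per the design text of the labels.

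A single table with 30282 mouse Ensembl genes was used. The submitters' processing notes name cutadapt 1.18, Bowtie2, STAR, SAMtools, deepTools, featureCounts and DESeq2 and the builds mm10 and dm6, without roles. The gene annotation and the strand setting are not given in the sources used here. The 4 library columns deposited by the authors are scores: read counts divided by 1 size factor per library and rounded to whole numbers, as worked out from the values. They are called normalised read counts in the report. The deposited mean column is a signal, the unrounded mean of these values over the 4 libraries. From this column the size factors came out as 0.88 and 0.87 for the untreated and 0.98 and 0.95 for the IAA libraries, and whole reads could be recovered for 100% of genes (tolerance 0.001 on the deposited mean, largest difference 5.0e-06). Whether the factors come from mouse reads or from the spike-in is not stated, and no Drosophila gene was among the rows used. The recovered reads gave median-of-ratios factors of 0.988, 0.992, 1.04 and 0.994 in the same order, while the deposited factors, divided by their geometric mean, are 0.958, 0.947, 1.07 and 1.03. The deposited scaling thus lowers the IAA libraries against the untreated ones. The authors also deposited a log2 fold change with its standard error, a Wald statistic score, p-values and adjusted p-values from DESeq2, per the name of the file, and a label of up or down. Values taken from these are named as the authors' deposited table.

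The design fixed before the data were examined foresaw a count test on recovered reads as an alternative. Because the columns are scaled and rounded, no count test was run, and limma's voom on recovered reads took its place, added after seeing the data. Genes with a mean of at least 10 over the 4 libraries (14928 genes; 15354 were left out) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, using an empirical Bayes trend, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The replicate numbers were not used to pair libraries. In fits without 1 library the lone library of its group is assumed to vary like the other group. Values per group are the mean ± SD of 2 libraries.

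A total of 29 gene lists was fixed before the data were examined. They cover cytosolic and mitochondrial ribosomal proteins, RNA polymerase subunits, transcription factors and cofactors, TOP mRNAs, ribosome biogenesis, pluripotency and lineage markers, feeder cells, stress responses, short-lived mRNAs, energy metabolism, cholesterol synthesis, the cell cycle, histones, splicing, the proteasome, interferon and aryl hydrocarbon receptor targets. Each was tested with camera (correlation between genes preset to 0.01, two-sided, adjusted over lists) and again with an estimated correlation. Ribosomal protein genes were also compared with 10000 random lists of the same size, matched on mean expression in 20 bins. The two-sided p of such a comparison, called permutation p below, comes from random draws of genes. It takes genes as independent and measures no spread between libraries. Named genes were chosen by a rule fixed beforehand: Polr2c; the 12 largest rises and 12 largest falls among called genes with a mean of at least 100 and groups that do not overlap, leaving out predicted genes and pseudogenes by symbol; and per list the 3 called members with the largest change, or the 2 of highest expression where none was called, with the highest and lowest member of the ribosomal protein and RNA polymerase II lists. Any gene named outside it is said to have been named after its values were seen.

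Alternatives fixed beforehand were other thresholds of adjusted p (0.01 and 0.1), a log2 fold change of at least 1, no filter or a mean of at least 100, pseudocounts of 0.5 and 5, leaving out each library, the replicate number as a block, leaving out predicted genes and pseudogenes, other list statistics, and re-centred fold changes. Median-of-ratios factors, library totals, unrounded values, voom on recovered reads and the authors' own tests were added after seeing the data. Coordinates and gene structures are those of GENCODE M21 on GRCm38, the assembly also called mm10, in which 30214 of the identifiers were found, and 8955 of the 9009 blank symbols were filled from it. The fits were tested on simulated data made from the real means, the size factors and 1 common dispersion (0.000816) taken from the replicates. In them 200 of 14925 tested genes were changed. The percentage recovered was 40 at a fold of 1.25, 64 at 1.5, 90 at 2 and 100 at 4 (50 genes each), with 0 unchanged genes called. A ribosomal protein list with a true change of -0.322 on the log2 scale came out at -0.321, and 3 of 100 random lists of unchanged genes had a matched-list p under 0.05. Genes were drawn independently of each other with that dispersion. The simulation therefore cannot check list tests of correlated genes or calls of genes with a wider spread. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.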

Results

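Poly(A) RNA was sequenced from V6.5 mouse embryonic stem cells, cultured with inhibitors of GSK3 and MEK, that carried RPB3 fused to a minimal auxin-inducible degron and GFP. RPB3, encoded by Polr2c, is a core subunit of RNA polymerase II. Doxycycline at 1 µg/ml for 12 h induced TIR1, the plant F-box protein that recognises the degron. The untreated group (2 libraries) received doxycycline alone, and the IAA group (2 libraries) then received the auxin indole-3-acetic acid at 500 µM for 12 h, according to the sample labels. The comparison asks how polyadenylated transcripts differ once RPB3 is degraded, and the title of the series points to ribosomal protein genes. The whole reads recovered from the table summed to 8724737 and 8794680 in the untreated libraries and to 9194432 and 8779401 in the IAA libraries. Replicates of a group lay far closer together than the groups did. A chi-square per gene, which is near 1 for counting error alone, was 1.40 between the untreated libraries and 1.24 between the IAA libraries, against 9.38 to 9.89 between libraries of different groups. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

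After IAA, 4312 of the 14928 genes tested were lower and 1650 were higher at the scale of the deposited table, while Polr2c mRNA itself was slightly higher. Polr2c (ENSMUSG00000031783, chromosome 8, 94857450 to 94873535, GRCm38) had normalised read counts of 2726 and 2885 in the untreated libraries and 3242 and 3158 in the IAA libraries. Its mean went from 2806 ± 112 (SD, n = 2) to 3200 ± 59.4 (SD, n = 2), a log2 fold change of 0.19 (SE 0.04; limma adjusted p = 0.00116), which in the authors' deposited table has an adjusted p of 0.113. An mRNA level does not measure the degraded protein, so it does not check the labels, and some Polr2c exon sequence overlaps Dok4. Most changes were small. The median log2 fold change was -0.40 among the genes called lower and 0.33 among those called higher, and 312 genes fell and 150 rose by a log2 fold change of at least 1. The median over all genes tested was -0.11. Its size depends on the scaling. Median-of-ratios factors, which place the median near 0 by construction, gave -0.01 and a split of 3036 higher and 3054 lower, that is 49.9% of calls higher in place of 27.7%. The genes called differed too, as 4700 of the 5962 called at the deposited scaling were also called with those factors. Whether total mRNA fell was not tested here. Medians of gene groups below are at the deposited scaling unless given against other genes.

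The steepest falls included Utf1 and Pdk1. Utf1, a chromatin-bound factor of undifferentiated stem cells (chromosome 7, 139943789 to 139945112, GRCm38), went from 954 ± 84.9 to 267.5 ± 33.2 (SD, n = 2 per group), a log2 fold change of -1.83 (SE 0.09). Pdk1, a kinase that restrains pyruvate dehydrogenase (chromosome 2, 71873224 to 71903858), went from 889.5 ± 17.7 to 295.5 ± 30.4, a log2 fold change of -1.59 (SE 0.08). Others among the 12 largest falls were Kifc3 (-1.50), Adam19 (-1.37), Inhbb (-1.36), Sptb (-1.35), Wwox (-1.34), Hpcal1 (-1.28), Ntn1 (-1.28), Aspg (-1.27) and Pnma2 (-1.27). Inhbb encodes an activin subunit and Ntn1 a secreted guidance cue. The 12 largest rises were led by 2 genes of zinc finger and membrane proteins. Zfp612 (chromosome 8, 110079746 to 110092741) went from 70.5 ± 2.12 to 232.5 ± 9.19, a log2 fold change of 1.71 (SE 0.13), and Neto2, an auxiliary subunit of kainate receptors, from 61.5 ± 12.0 to 190.0 ± 26.9, a log2 fold change of 1.62 (SE 0.16). H1f0, an intronless linker histone gene (chromosome 15, 79028450 to 79030504), went from 1208 ± 105 to 2807 ± 112, a log2 fold change of 1.22 (SE 0.06). Tarm1 (1.35), Mfsd2b (1.10), Zfp977 (1.10), Srxn1 (1.10), Zfp386 (1.09), Hoxc12 (1.02), Eif4g3 (0.99) and Zmiz1 (0.97) were also among them. The genes named here passed in limma, with adjusted p from 1.44e-11 to 4.41e-06, kept their direction with median-of-ratios factors, and were also called in the authors' deposited table.

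**Figure D1:**
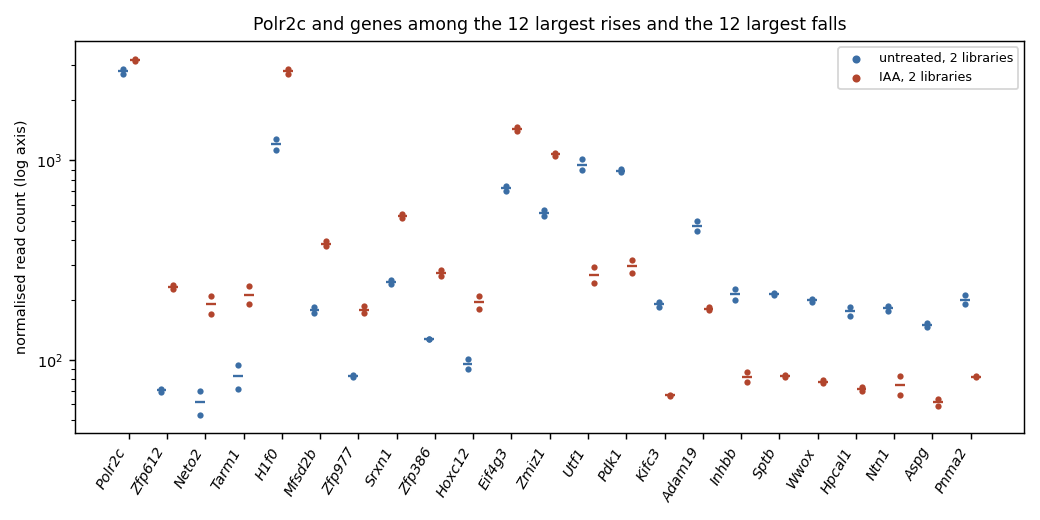
Normalised read counts (log axis) of Polr2c and of genes among the 12 largest rises and the 12 largest falls; each point is a library, and the short line is the mean of 2 libraries of the untreated (blue) or IAA (red) group. Apart from Polr2c, the genes were chosen from those whose 2 groups do not overlap, and in Polr2c they do not overlap either. Utf1 lies at 894 and 1014 in the untreated and at 244 and 291 in the IAA libraries.

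Nearly all cytosolic ribosomal protein genes fell together and by similar amounts. Of 79 members tested, 76 were lower, none was higher and 3 did not pass, with a median log2 fold change of -0.36. Rpl7a went from 8006 ± 113 to 5586 ± 7.07 (SD, n = 2 per group; log2 fold change -0.52, SE 0.03), Rps29 fell by 0.48 and Rps28 by 0.48 on the log2 scale. Among those that did not pass were Rpl24 (0.57, SE 0.43) and Rps10 (0.15), the latter named after its values were seen. Rpl24 was read at only 8.5 and 13.5 in the 2 groups, and its exons overlap the annotated gene Gm28037, so that count does not stand for Rpl24 as a whole. Ribosomal protein genes took 4.86% and 4.91% of all deposited values in the untreated libraries and 4.10% and 4.09% in the IAA libraries. The median of the list lay 0.25 below that of all other genes on the log2 scale (difference -0.25). It lay outside the central 95% of 10000 random lists matched on mean expression (-0.05 to 0.07, two-sided permutation p = 2e-04, the smallest these lists can give). That p takes genes as independent, whereas the estimated correlation between the members was 0.249. In camera, limma's competitive list test, the adjusted p was 3.48e-34 with the preset correlation between genes, and adjusted p = 0.643 (p = 0.0661 before adjustment) with an estimated correlation. With median-of-ratios factors 75 members were lower and none higher. At an adjusted p under 0.05 in the authors' deposited table, 74 were lower. A total of 59 members have a copy in the table named as a -like gene or pseudogene, with which they can share reads. The other 20 lay at -0.29 against all other genes. Copies under other names were not looked for, so these 20 may share reads too.

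Among other translation components the TOP mRNAs fell and the remaining lists were mixed. All 26 tested translation factors and further mRNAs with a 5' terminal oligopyrimidine (TOP) motif were lower, with a median of -0.32, or -0.22 against other genes (camera adjusted p = 7.04e-15; adjusted p = 0.643 with an estimated correlation), and 22 were lower with median-of-ratios factors. Among them Eef2, the translocation factor of the ribosome, went from 29040 ± 134 to 20890 ± 102 (log2 fold change -0.47, SE 0.03), Hnrnpa1 had -0.63 and Vim, an intermediate filament gene on the list for its TOP motif, -0.59. Mitochondrial ribosomal protein genes, which carry no such motif as a class, were mixed: 32 of 77 were lower and 6 higher (34 and 8 adjusted over the list alone), among them Mrpl48 (-0.81), Mrps10 (-0.64) and Mrps28 (-0.47), and the list was not called among the tested genes (adjusted p = 0.262) but was called lower with no filter on low values (adjusted p = 0.00268), a setting not run with an estimated correlation, which for the tested genes gave adjusted p = 0.889. With median-of-ratios factors they were 17 lower and 13 higher. Ribosome biogenesis genes did not stand apart (adjusted p = 0.958). Utp14a (-0.68) and Dkc1 (-0.43) fell and Nop58 rose (0.31), and the count of 14 lower and 6 higher of 50 turned to 10 lower and 20 higher with median-of-ratios factors.

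**Figure D2:**
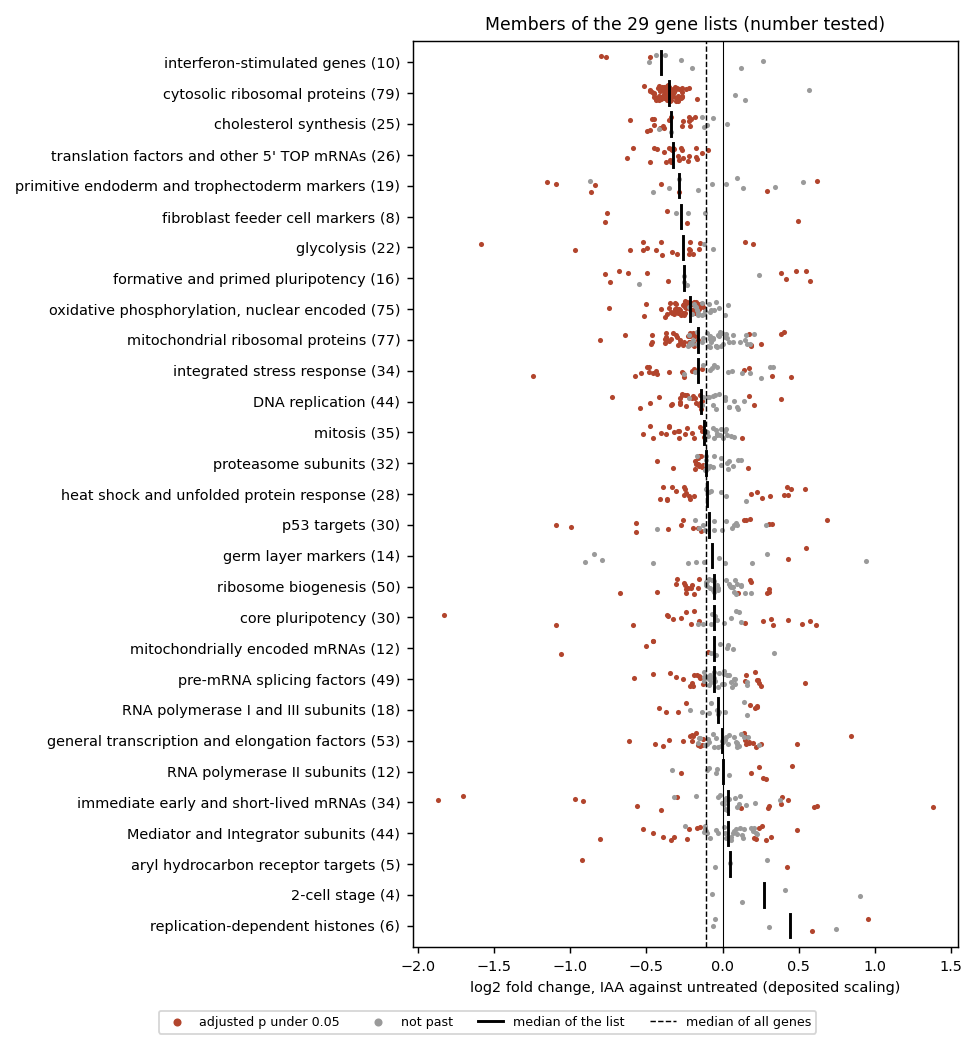
Log2 fold change of each tested member of the 29 gene lists, IAA against untreated, at the deposited scaling; red points passed an adjusted p under 0.05 in limma, the short black line is the median of a list and the dashed line the median of all genes tested (-0.11). Cytosolic ribosomal protein genes (median -0.36) and the TOP list (median -0.32) form narrow groups left of the dashed line, while core pluripotency genes spread from -1.83 to 0.61.

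Genes of the transcription machinery moved in both directions. Of the 12 RNA polymerase II subunits, 5 were higher, Polr2j (0.46), Polr2a (0.29), Polr2d (0.26), Polr2l (0.24) and Polr2c (0.19), and Polr2i was lower (-0.27). Polr2d and Polr2l were named after their values were seen. Polr2a, the gene of the largest subunit, went from 9970 ± 145 to 12160 ± 178 (SD, n = 2 per group). Polr2k had the lowest value, -0.33, and did not pass. The list was not called at the deposited scaling (camera adjusted p = 0.0745) and was called higher with median-of-ratios factors (adjusted p = 0.0122), where 6 members were higher and Polr2i no longer passed. With an estimated correlation, at the deposited scaling, it was not called (adjusted p = 0.643). Adjusted over the list alone, 5 were higher and 2 lower. General transcription and elongation factors gave 11 higher and 14 lower of 53 (12 and 14 adjusted over the list alone; 22 and 5 with median-of-ratios factors), with an adjusted p of 0.15 that became 0.0121 with those factors and was 0.785 with an estimated correlation at the deposited scaling. Hexim1, whose protein holds the elongation kinase P-TEFb inactive, had the largest rise of the list (0.85, SE 0.07), Gtf2h1 rose (0.49), and Mnat1, a subunit of the CDK7 kinase, fell (-0.62). Mediator and Integrator subunits had 7 higher and 10 lower of 44 (21 and 7 with median-of-ratios factors; adjusted p = 0.15), with Med20 (-0.81), Ints7 (-0.52) and Ints6 (0.49) as the widest. RNA polymerase I and III subunits had 4 higher and 4 lower of 18 (5 and 5 adjusted over the list alone; 6 and 3 with median-of-ratios factors; adjusted p = 0.663), the lower ones including Polr3gl (-0.42), Polr1c (-0.37) and Polr3b (-0.29). Splicing factors had 8 higher and 14 lower of 49, which turned to 21 and 8 with median-of-ratios factors (adjusted p = 0.681, 0.0468 in favour of a rise with those factors, and 0.948 with an estimated correlation at the deposited scaling). Prpf3 rose (0.55) and Snrpa (-0.58) and U2af1 (-0.46) fell.

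Many genes of glycolysis, oxidative phosphorylation and sterol synthesis were lower, while mitochondrially encoded mRNAs were mixed. In glycolysis 18 of 22 were lower and 2 higher (19 and 2 adjusted over the list alone; 15 and 2 with median-of-ratios factors), with a median of -0.26, or -0.15 against other genes (camera adjusted p = 8.34e-07; adjusted p = 0.643 with an estimated correlation). Besides Pdk1, which acts downstream of glycolysis, Aldoc (-0.97) and Pfkp, a phosphofructokinase (-0.61, from 6060 ± 91.2 to 3970 ± 7.78, SD, n = 2 per group), fell most. Nuclear genes of oxidative phosphorylation had 55 of 75 lower and none higher by limma (59 lower adjusted over the list alone; 33 lower and none higher with median-of-ratios factors), with a median of -0.21, or -0.11 against other genes (adjusted p = 6.38e-09; adjusted p = 0.643 with an estimated correlation). Atp5e (-0.75), Ndufa7 (-0.52) and Sdhb (-0.51) fell most. Of the 12 mitochondrially encoded mRNAs tested, 5 were lower and none was higher (6 and 1 adjusted over the list alone; list adjusted p = 0.741). The lower ones included mt-Nd3 (-1.06, from 38.5 to 18.0), mt-Atp6 (-0.50, from 156 to 110) and mt-Co3 (-0.46, from 101.5 to 74.0). Among the 7 that did not pass were mt-Nd1 (0.03) and mt-Co1 (0.07), named after their values were seen. In the authors' deposited table no member had an adjusted p under 0.05. With median-of-ratios factors 2 were lower and 4 higher. In cholesterol synthesis 18 of 25 were lower and none higher (19 lower adjusted over the list alone), with a median of -0.34, or -0.23 against other genes (adjusted p = 1.88e-05; adjusted p = 0.643 with an estimated correlation), led by Msmo1 (-0.61), Tm7sf2 (-0.50) and Nsdhl (-0.47). With median-of-ratios factors 13 were lower and 1 higher.

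Many cell-cycle genes were lower, and the calls of their lists depended on the scaling. DNA replication genes had 23 of 44 lower and 3 higher (25 and 3 adjusted over the list alone; 13 and 8 with median-of-ratios factors), with a median of -0.14, or -0.04 against other genes. Tk1, the thymidine salvage kinase, went from 768.5 ± 10.6 to 465.0 ± 5.66 (-0.72), and the polymerase delta genes Pold1 (-0.54) and Pold2 (-0.48) followed. The camera adjusted p was 0.0291 at the deposited scaling, 0.262 with median-of-ratios factors and adjusted p = 0.643 with an estimated correlation. Mitosis genes, with a median of -0.01 against other genes, had 18 of 35 lower and 1 higher (14 and 5 with median-of-ratios factors), among them Aurkb (-0.52), Hmmr (-0.48) and Cenpa (-0.46), with an adjusted p of 0.00838, of 0.134 with median-of-ratios factors and adjusted p = 0.643 with an estimated correlation. Only 6 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, were tested. H1f2 (0.96) and H2bc4 (0.59) rose and the list was not called (adjusted p = 0.0854). Proteasome subunits had 13 of 32 lower, such as Psma3 (-0.43), Psmd3 (-0.32) and Psmb7 (-0.18), and 1 higher (14 and 1 adjusted over the list alone), which turned to 2 lower and 7 higher with median-of-ratios factors (list adjusted p = 0.262).

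Stress lists showed no common direction except a weak call for the integrated stress response. There 16 of 34 were lower and 4 higher (17 and 4 adjusted over the list alone; 12 and 6 with median-of-ratios factors). The lower ones were led by Cbs (-1.24), Aldh1l2 (-0.58) and Phgdh (-0.53), enzymes of sulphur amino acid, folate and serine metabolism. The adjusted p was 0.0493, 0.0514 with median-of-ratios factors and adjusted p = 0.643 with an estimated correlation. Heat shock and unfolded protein response genes had 9 higher and 13 lower of 28 (10 and 14 adjusted over the list alone; 12 and 11 with median-of-ratios factors; adjusted p = 0.681). The inducible chaperones Hspa1a (0.54), Hspa1b (0.45) and Dnajb1 (0.43) rose. p53 targets had 6 higher and 11 lower of 30 (6 and 12 adjusted over the list alone; 8 and 6 with median-of-ratios factors; adjusted p = 0.97), with Ddit4l (-1.09) and Pvt1 (-0.99) lower and Sertad1 (0.69) higher. Immediate early and other short-lived mRNAs had 9 higher and 7 lower of 34 (10 and 7 adjusted over the list alone; 12 and 7 with median-of-ratios factors; adjusted p = 0.0854). Spry4 went from 91.5 ± 2.12 to 24.5 ± 4.95 (-1.87, SE 0.22) and Dusp4 from 98.5 ± 0.707 to 29.5 ± 2.12 (-1.71, SE 0.20). Both encode feedback inhibitors of ERK signalling, and Per2, a clock gene, was higher (1.39, SE 0.42) at a low level. Of 10 interferon-stimulated genes tested, Ddx58 (-0.80), Stat2 (-0.77) and Bst2 (-0.48) were lower and none was higher (1 higher with median-of-ratios factors; list adjusted p = 0.15). Targets of the aryl hydrocarbon receptor, for which indole compounds can be ligands, had Nqo1 higher (0.42) and Aldh3a1 lower (-0.93) of 5 tested (adjusted p = 0.318). No library with IAA and without the degron was analysed here.

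Core pluripotency genes split. Of 30 tested, 8 were higher and 11 lower (9 and 11 adjusted over the list alone; 13 and 9 with median-of-ratios factors; list adjusted p = 0.573). Besides Utf1, the RNA-binding protein gene Lin28a went from 1466 ± 79.9 to 684 ± 39.6 (-1.10, SE 0.06), and Prdm14, a repressor that guards the naive state, from 485 ± 32.5 to 742 ± 14.1 (0.61, SE 0.07). Formative and primed genes had 5 higher and 6 lower of 16 (list adjusted p = 0.663), with Sox3 (-0.78), Dnmt3l (-0.74) and Pou3f1 (-0.68) lower. None of the 4 tested 2-cell stage genes passed in limma at the deposited scaling (list adjusted p = 0.291), where Zscan4d had 0.90 (SE 0.40; adjusted p = 0.0753) and Usp17le 0.13; Zscan4d passed with median-of-ratios factors (adjusted p = 0.0296). Primitive endoderm and trophectoderm markers had 6 of 19 lower and 2 higher (list adjusted p = 0.318). Hnf4a (-1.15) and the basement membrane genes Col4a2 (-1.09) and Lama1 (-0.86) were lower. Among 14 germ layer markers Nes rose (0.55) and none fell (list adjusted p = 0.262). Markers of fibroblast feeder cells, another cell type such cultures can hold, had 4 of 8 lower, including Thy1 (-0.78) and Col1a1 (-0.76), and Loxl1 higher (0.50) (5 lower and 1 higher adjusted over the list alone; list adjusted p = 0.262).

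The list test compares members with other genes, so 8 of 29 lists were called with the preset correlation and none with an estimated one, for which the 4 libraries leave 2 residual degrees of freedom and no list had an unadjusted p under 0.05. For 12 lists the counts adjusted over the list alone were those over all genes tested. The median of formative genes lay below that of other genes while their test pointed up, and the medians of p53, heat shock and mitochondrially encoded lists lay above it while their tests pointed down. Mediator, immediate early and aryl hydrocarbon receptor lists had a median above 0 and a mean below 0.

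The authors' deposited table gives 284 genes as higher and 1100 as lower at an adjusted p under 0.05. All 1384 of them were also called here in the same direction, so the count of 5962 rests on limma. The authors' labels mark 14 genes as up and 67 as down, none with an absolute log2 fold change under 1.002. At an absolute log2 fold change of at least 1, limma called 150 higher and 312 lower. That table gives fewer members of most lists as lower than limma does: 21 of the TOP list, 15 of oxidative phosphorylation, 13 of glycolysis, 9 of cholesterol synthesis, 10 of DNA replication, 11 of mitosis, 11 of the integrated stress response and 5 of the mitochondrial ribosomal proteins. Higher members are fewer there too. It gives 1 RNA polymerase II subunit (5 in limma), 2 general transcription and elongation factors (11) and 1 Mediator or Integrator subunit (7) as higher. The same holds for 2 heat shock and unfolded protein response genes (9) and 2 immediate early and short-lived mRNAs (9). Of the 104 named genes that passed in limma, 74 also had an adjusted p under 0.05 by the authors' test, and 25 did not. Among these 25, by the authors' adjusted p, were Polr2j (0.129), Polr2i (0.482), Hspa1a (0.453), Atp5e (0.131) and Pou3f1 (0.15). The authors' test gives no adjusted p for 8 of all 108 named genes. When any 1 library was left out, limma called none of the genes at an adjusted p under 0.05 (4734 to 5070 at an unadjusted p under 0.05), because rounding gave 361 to 372 genes a variance of 0 with 1 residual degree of freedom. On the unrounded values the same 4 fits called 4829 to 5347 genes, and voom on recovered reads 4749 to 5268. Of the 104 named genes that passed, 91 also passed in all 4 fits on unrounded values. The strand setting of the counting is not given in the sources used here, so genes whose exons overlap another gene, such as Sptb with Plekhg3, Polr2j with Lrwd1, Mrpl48 with Rab6a, Tk1 with Afmid, Rps28 with Kank3, Dnmt3l with Aire and Col4a2 with Col4a1, can hold reads of both.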

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

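Data outside the tested genes also differed between the groups. The 15354 genes below the tested level held a mean of 0.3407% of the IAA library totals against 0.3185% of the untreated totals (0.344% and 0.337% against 0.323% and 0.314%), and the groups did not overlap, as happens by chance in 33.3% of measures with 2 libraries a group. More of these genes had at least 1 read after IAA, 10272 and 10093 against 9513 and 9535. At 0 in both untreated libraries and at least 3 in both IAA libraries were 27 genes, and 11 showed the reverse.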

How the results depend on the processing

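Unrounded values, voom, median-of-ratios factors, library totals and the authors' own tests were chosen after seeing the data. In the matched-list test the difference of ribosomal protein genes from other genes kept its direction and its side of the threshold under each alternative run, from -0.317 to -0.241. In camera the list lost its call with an estimated correlation (adjusted p = 0.643). Only 4557 to 4700 of the 5962 genes changed were also called under other scalings. The number changed stayed between 4097 and 7087 under other adjusted p thresholds, scalings, pseudocounts, the filter at 100, voom, unrounded values, the block and without predicted genes. It was 462 with a log2 fold change of at least 1, 817 with no filter (2542 on unrounded values; with the low genes limma's prior degrees of freedom dropped from 18.0 to 1.20), 1384 in the authors' deposited table and 1271 with the authors' p-values adjusted over the genes tested here. Without 1 library limma called 0 in each of 4 fits, with 4734 to 5070 at an unadjusted p under 0.05. The same fits called 4829 to 5347 genes on unrounded values, which shows rounding as the cause, and 4749 to 5268 with voom. The share of calls that were higher was 27.7%, 49.9% with median-of-ratios factors, 50.8% with library totals and 47.9% re-centred. The median shift (-0.107) was -0.082 and -0.08 over genes with a mean of at least 1 and 1000, -0.014 re-centred, -0.007 with median-of-ratios factors and -0.003 with library totals, as those scalings set it.

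Of the 29 lists, 8 were called, 0 with an estimated correlation, 2 with the log2 fold change as statistic (ribosomal proteins, adjusted p = 0.0089, and replication-dependent histones, 0.0274), 6 with predicted genes left out, 7 with the rank test, and 5 to 7 without 1 library (5 without IAA replicate 2). Ribosomal protein, TOP, glycolysis, oxidative phosphorylation and cholesterol lists were called without any 1 library, but all except ribosomal proteins lost their call with the log2 fold change as statistic (TOP 0.152, glycolysis 0.121, oxidative phosphorylation 0.293, cholesterol 0.194). The integrated stress response lost its call in the rank test (0.153) and without each library (adjusted p from 0.0562 to 0.333), DNA replication without untreated replicate 2 (0.0767), IAA replicate 1 (0.0607) and IAA replicate 2 (0.11) and at a mean of at least 100 (0.076), and mitosis without untreated replicate 1 (0.107) and IAA replicate 2 (0.0718). Immediate early mRNAs gained a call without untreated replicate 2 (0.021) and at a mean of at least 100 (0.037). With no filter 11 lists were called, gaining mitochondrial ribosomal proteins (0.00268), 2-cell stage (0.0109) and proteasome (0.0132). Medians of lists against other genes that changed sign, none of them called in that setting, were, with no filter, ribosome biogenesis -0.019, core pluripotency -0.019, p53 targets -0.02, heat shock -0.061, mitochondrially encoded -0.001, splicing -0.016 and interferon 0.102, and at a mean of at least 100, formative genes 0.169 and heat shock -0.016. Without 1 library they ranged from -0.023 to 0.119 for core pluripotency, -0.02 to 0.045 for p53 targets, -0.085 to 0.013 for the integrated stress response, -0.031 to 0.037 for heat shock, -0.037 to 0.02 for mitosis and -0.024 to 0.025 for the proteasome; the uncalled gene Usp17le ranged from -0.297 to 0.551. The cause was not tested. Of the 104 called named genes, none changed sign in the fits on unrounded values without 1 library; 13 lost their call in at least 1 of them, including Aldh3a1, Col1a1, H1f2, Hspa1a, Loxl1, Per2, Sox3 and mt-Nd3. With median-of-ratios factors Polr2i, Aldh1l2, mt-Co3 and Psmb7 lost theirs.

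The replicate number as a block gave 5958 genes and changed no list call. Replicate differences did not correlate between groups (0.002, and -0.065 at a mean of at least 100), so no effect shared by replicate number was seen. Replicates differed by little more than counting error (chi-square per gene 1.40 and 1.24). The correlation therefore cannot show whether the numbers pair the libraries. A count test with edgeR on recovered reads was not run.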

Other observations

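Apart from the expression-matched test of ribosomal protein genes, which was fixed beforehand, the tests in this part were chosen after the list results had been seen, and the tests of the size factors and of the authors' standard errors after their own values had been seen. Gene structure went with the direction of change among the 13059 protein-coding genes tested. Of 264 genes with a body over 300 kb, 118 were lower and 12 higher, with a median log2 fold change of -0.38, which is -0.27 against other protein-coding genes (matched lists -0.08 to 0.03; two-sided permutation p = 2e-04, the smallest 10000 lists can give). Genes of 100 to 300 kb had a median of -0.15, and those under 10 kb, of 10 to 30 kb and of 30 to 100 kb -0.10, -0.10 and -0.10. Wwox, among the largest falls, spans more than 300 kb. Single-exon genes went the other way: 68 of 271 were higher and 27 lower, with a median of 0.13, against 11.4% higher and 31.6% lower of the multi-exon genes. With median-of-ratios factors the medians were -0.28 for the longest genes and 0.23 for single-exon genes.

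Zinc finger genes named Zfp, many of which encode KRAB repressors, had 56 of 340 higher and 50 lower, a median 0.16 above that of other protein-coding genes (permutation p = 2e-04; 102 higher and 34 lower with median-of-ratios factors). Host genes of small nucleolar RNAs named Snhg had 7 of 13 lower and none higher in limma (5 lower and 1 higher with median-of-ratios factors). Solute carriers named Slc had 86 of 248 lower and 31 higher, which did not stand apart (-0.06 against other protein-coding genes, permutation p = 0.108). Pseudogenes named after ribosomal proteins had 21 of 46 lower and none higher, with a median of -0.45, close to the fall of the genes whose reads they can share.

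The joint fall of ribosomal protein genes was weighed against 3 technical explanations. Expression level would place the list within lists matched on it, yet its difference of -0.25 lay outside -0.05 to 0.07. Lists drawn from the 50 genes nearest to each member in expression, transcript length and GC content had medians from -0.22 to -0.15 (central 95%), above the -0.355 of the list, so these account for part of the fall at most; the match was incomplete, with a median transcript of 1148 against 914 bases and a median level of 2450 against 5056. A size factor moves all genes of a library alike, so the fall relative to other genes could not depend on it. The plain fall does depend on it in part. The list median was -0.355 at the deposited scaling and -0.254 with median-of-ratios factors, where 94.9% of members were still called lower. Loss of RPB3 and an effect of IAA itself both stay open, and IAA on cells without the degron would separate them. The IAA group received IAA after its 12 h of doxycycline. Time since induction may therefore also differ between the groups, which cannot be told apart here.

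The trends with gene structure were weighed likewise. Transcript length, GC content, expression and the single-exon term were put in 1 model. In it the slope per 10-fold gene length was -0.126 (95% bootstrap interval over genes -0.144 to -0.107), against -0.06 unadjusted. With gene length in the model the single-exon term was 0.186 (0.119 to 0.246), against an unadjusted difference of 0.254. These properties thus do not remove either trend, although they change the size of both. The slope is a linear summary, while the medians by gene length were alike up to 100 kb and lower only above it. Genomic DNA in the IAA libraries would raise silent genes too. Summed over 23 silent single-exon receptor genes the values were 20 and 26 in the untreated and 29 and 19 in the IAA libraries, a rise per kb that is 0.117% of the median rise of the single-exon genes called higher (29.8 per kb). Long genes may fall because elongation through them takes longer when polymerase is limiting, a hypothesis that these steady-state levels did not test and that nascent RNA along the gene bodies would decide.

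The limma test called 5962 genes, against 1384 in the authors' deposited table. The filter of the authors on low genes does not account for the difference. The smallest mean with an adjusted p in their table was 42.76, and limma called 5257 of the 9727 genes with a mean of at least 100. Adjusting the authors' p-values over the genes tested here gave 1271, but adding low genes could hardly have raised that count. The authors' standard errors were a median of 2.25 times those of limma, and the differences between replicates, divided by the authors' standard error times the root of 2, had an SD of 0.465. The authors' standard errors were thus wider than the spread between these libraries. With limma's standard errors the same SD was 0.9902, but limma takes its errors from that very spread. The value of 0.465 therefore largely restates the ratio of the standard errors. It does not decide whether the spread between these libraries, which may be technical, is too narrow, and the reason for the difference stays open.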
